A study of Mus musculus with 8 samples.

How the data were processed

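Whole adipose tissue was sequenced in 8 samples from cold-exposed mice, 4 labelled WT and 4 labelled KO. Polyadenylated RNA was captured and libraries were made with dUTP in the second strand, per the labels' protocols. The deposited table holds 1 count per gene and library, as whole numbers, with 18395 genes. The genome build was GRCm39, per the submitters' processing notes. The aligner, the counting program and the annotation behind the counts are not given in the sources used here. Gene symbols were taken from the names in GENCODE release M21 and were found for 18321 genes, leaving 74 without one; 206 genes had 0 counts in all libraries. In the fixed gene lists, Ahsp was not matched to any gene in the table. The library totals are given in the report.

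Genes were kept by filterByExpr by group, which left 13901. Counts were scaled by the trimmed mean of M values (TMM), whose factors averaged 0.914 ± 0.0288 in WT and 1.09 ± 0.0447 in KO (SD, n = 4). KO was compared with WT by edgeR 4.0.16 in R 4.3.3, with the robust quasi-likelihood F test and group as the only term. P-values were adjusted by the method of Benjamini and Hochberg with a threshold of 0.05. CPM values use the TMM-scaled library sizes. Standard errors were derived from the log2 fold change and the F statistic.

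Before the data were examined, 55 gene lists were fixed, of which 53 had at least 5 tested members; those for epithelium and skin and for mesothelium had 2 each. Lists were tested by camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, then with an estimated correlation, and by fry. Members were also adjusted over the list alone. The named genes were Fermt2 and 12 genes named in advance (Ucp1, Ppargc1a, Dio2, Cidea, Prdm16, Adrb3, Elovl3, Pparg, Adipoq, Lep, Col1a1 and Adgre1). To these came up to 10 called genes with the largest rise and 10 with the largest fall, with a mean log2 CPM of at least 1 and every KO library on the same side of every WT library. In each list described, up to 4 called members with the smallest p were eligible, or the member with the smallest p where none was called. The same rule was applied to the 6-library comparison after the data were seen. Acta1, Gbp2 and Ddx3y were named after their values were seen. The values of 1 eligible gene and 1 test on KO replicate 2 are not reported here.

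The alternatives were DESeq2 1.42.0 factors, upper-quartile factors and total library size only, no filter and a stricter filter (CPM of at least 1 in 4 libraries), DESeq2, limma-voom with and without sample quality weights, and a fit without robust dispersion. Further ones were a replicate block, each library left out in turn, and removal of mitochondrially encoded genes or of muscle, erythroid and B cell list members. Fold change thresholds and an adjusted p under 0.01 were also tried. On the data, the DESeq2 test was run on all 18395 genes with its own default filtering, without filterByExpr. Added after the data were seen were the 6-library comparison, also with DESeq2 and with quality weights, an adjusted p under 0.10, and removal of length and GC trends. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

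The tests were checked on simulated counts with 200 changed genes among 13901. With 8 libraries edgeR recovered 1.49%, 28.4% and 75.8% of the genes changed 1.5-, 2- and 4-fold, with 6 false calls among 82. DESeq2 recovered 14.9%, 50.7% and 86.4%, with 52 false calls among 168. Limma-voom with quality weights made 5 false calls among 75. With 6 libraries edgeR recovered 10.4%, 58.2% and 87.9%, with 6 false calls among 126. Camera found the lowered tricarboxylic acid cycle list and called 0 of the 52 other lists. The simulated genes were drawn independently around a shared mean profile, so lists held no correlation between genes and no library stood apart. In the data the estimated correlation of the tricarboxylic acid cycle list was 0.60. The check therefore does not cover false calls among correlated lists or with outlying libraries.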

Results

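RNA was sequenced from mouse adipose tissue in 8 libraries, 4 from control mice (WT) and 4 from mice in which Kindlin-2 had been removed from brown adipocytes (KO). Kindlin-2 is a focal adhesion protein that binds integrins and is encoded by Fermt2. All mice had been kept at 4 °C for 6 hours, a cold challenge that switches on heat production in brown fat. The labels call the tissue adipose and do not name the depot. The total count per library ranged from 33672272 to 43253559 in WT and from 35734373 to 40927141 in KO. No label says whether the replicates of a group were separate animals, so p-values measure the spread between these samples. Y-linked transcripts such as Ddx3y were counted in all 8 libraries and Xist reached at most 12 counts in any.

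The series compares the genotypes under cold, to see what loss of Kindlin-2 in brown adipocytes does to cold tolerance. Fermt2 (ENSMUSG00000037712) was measured first, since it checks the labels. Its level was 239, 235, 244 and 201 CPM in WT replicates 1 to 4. In KO replicates 1 to 4 it was 192, 132, 173 and 174 CPM. All 4 KO libraries lay below all 4 WT libraries, with means of 230 ± 19.4 CPM in WT and 168 ± 25.3 CPM in KO (SD, n = 4). The log2 fold change was -0.45 ± 0.14 (SE), with an unadjusted p of 0.00813 and an adjusted p of 0.134 in edgeR, so the difference missed the threshold of 0.05 over all genes. DESeq2 gave an adjusted p of 0.0336 for the same gene. Which cells contribute the Fermt2 reads that remain in KO was not measured.

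**Figure D1:**
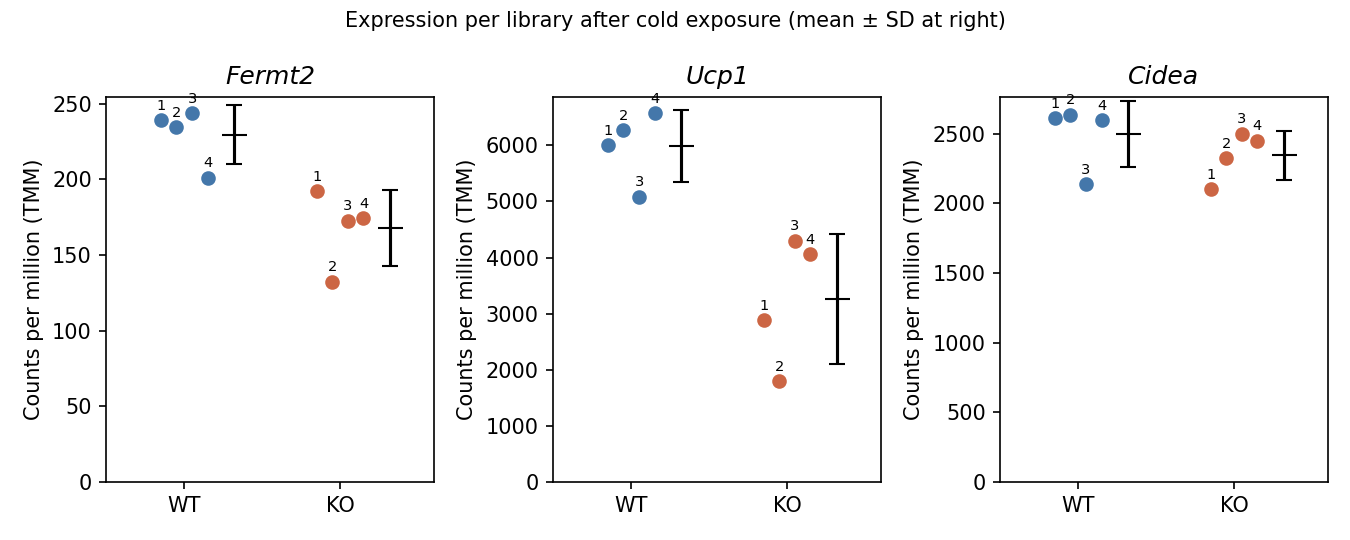
CPM of Fermt2, Ucp1 and Cidea (y axes, from 0) in the WT and KO libraries (x axes). Each point is 1 library, numbered by replicate, and the bar at the right of each group is the mean ± SD (n = 4). The KO points of Fermt2 and Ucp1 all lie below the WT points, and those of Cidea overlap with them.

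In KO tissue, most genes of several energy metabolism lists lay lower with TMM scaling. None of these lists passed with an estimated correlation (smallest adjusted p 0.310). All 20 measured genes of branched-chain amino acid breakdown, all 22 of the tricarboxylic acid cycle, 20 of 22 of fatty acid oxidation and 17 of 18 of peroxisomal fatty acid metabolism lay lower in KO, with list medians between -0.54 and -0.62 on the log2 scale. The 13 mRNAs encoded by mitochondrial DNA all lay lower as well, with a median log2 fold change of -0.77. Ucp1, the uncoupling protein that releases respiratory energy as heat, averaged 5983 ± 645 CPM in WT and 3258 ± 1158 CPM in KO (SD, n = 4). Endothelial markers lay on the other side: 19 of 20 were higher in KO, with a median log2 fold change of 0.57.

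No single gene passed the test over all genes. At an adjusted p under 0.05, edgeR's quasi-likelihood test called 0 of 13901 genes (smallest adjusted p 0.0800), although 2993 genes had an unadjusted p under 0.05 where 695 would be expected by chance. Limma-voom also called 0, and limma-voom with sample quality weights called 911 (408 higher and 503 lower in KO). Those weights were 2.38 and 2.08 for KO replicates 3 and 4, against 0.518 and 0.337 for KO replicates 1 and 2. The KO side of that fit thus leaned on replicates 3 and 4, which were also the most alike pair of libraries (Spearman correlation 0.9935). DESeq2, run on all 18395 genes without that filter, called 1113 (511 higher and 602 lower). Of 55 gene lists fixed before the data were examined, 53 had enough measured members, and camera called 23 of them, 6 higher and 17 lower in KO. None of the 23 passed with an estimated correlation between genes (smallest adjusted p 0.310), and fry called 9.

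A pair of libraries stood apart from the rest. In WT replicate 3, the skeletal muscle list took 4.78% of all counts, against 0.00431% to 0.0381% in the other 7 libraries. The actin of skeletal muscle, Acta1, reached 11195 CPM there and 57.3 CPM at most elsewhere. In KO replicate 2, the interferon response list took 0.553% of all counts, against 0.117% to 0.219% elsewhere. The interferon-induced GTPase Gbp2 reached 1505 CPM in that library and 54.2 CPM at most elsewhere, and T and NK cell transcripts took 0.0326% of counts against at most 0.00637%. The median Spearman correlation with the other libraries was 0.932 for WT replicate 3 and 0.958 for KO replicate 2, against 0.969 to 0.981 for the other 6.

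**Figure D2:**
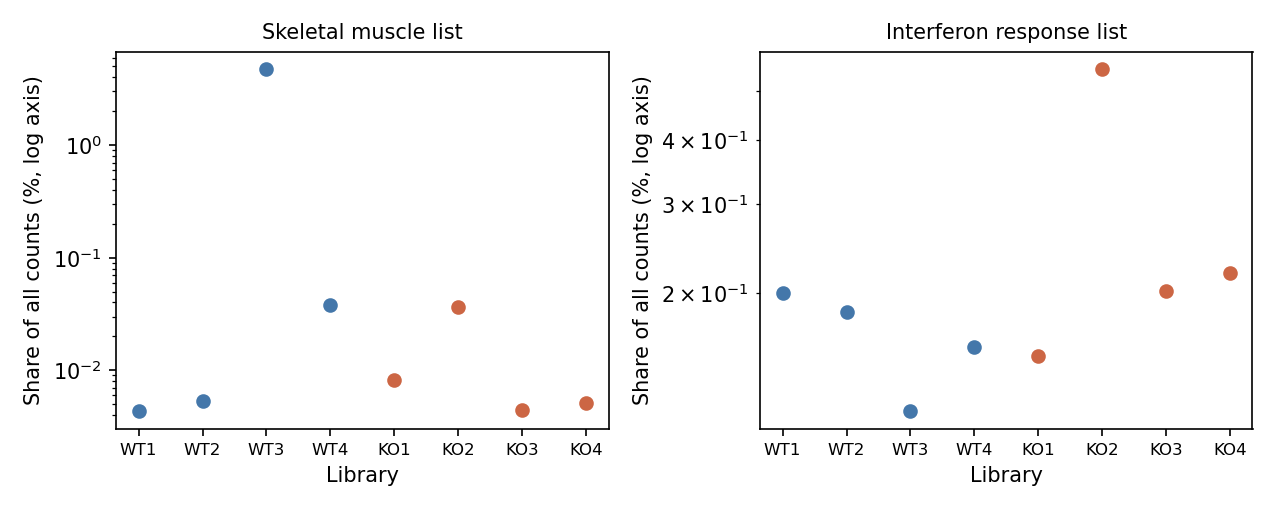
Share of all counts (y axes, percent, log scale) taken by the skeletal muscle list and the interferon response list in each library (x axes). Each point is 1 library, blue for WT and orange for KO. WT replicate 3 stands at 4.78% for the muscle list and KO replicate 2 at 0.553% for the interferon list.

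Without these 2 libraries, 3 remained per group and edgeR called 461 of 13901 genes, 253 higher and 208 lower in KO. This fit, added after the data were seen, is called the 6-library comparison. Of the 461 genes, 455 had the same direction with all 8 libraries, which is largely built in because the 6 libraries are among the 8. With all 8 libraries 142 of the 461 had an edgeR adjusted p under 0.10. The biological coefficient of variation was 0.226 in the 6-library comparison and 0.361 with all libraries. KO replicate 2 accounted for most of the difference in the number of calls. Leaving out that library alone gave 361 calls, and leaving out WT replicate 3 alone gave 0.

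Branched-chain amino acid catabolism, by which valine, leucine and isoleucine enter the mitochondrial acyl-CoA pool, was the list with the smallest camera p (adjusted p = 6.64e-12). Adjusted over the list alone, 18 of its 20 genes fell. Over all genes tested the number called was 0 with all 8 libraries and 11, all lower, in the 6-library comparison. Mccc2, a subunit of methylcrotonyl-CoA carboxylase, averaged 96.9 CPM in WT and 61.1 CPM in KO, a log2 fold change of -0.67 ± 0.10 (SE; edgeR adjusted p = 0.0874, and 0.0334 with 6 libraries). Ivd, isovaleryl-CoA dehydrogenase, differed by -0.71 ± 0.12 (adjusted p = 0.0874, and 0.0289 with 6 libraries). Hibch, a hydrolase of the valine branch, differed by -0.68 ± 0.13 (adjusted p = 0.0915, and 0.0289). Bckdha, part of the dehydrogenase complex that commits these acids to breakdown, differed by -1.21 ± 0.26 (adjusted p = 0.0981, and 0.0329). The list's adjusted p was 0.334 with an estimated correlation and 0.0253 by fry.

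In the tricarboxylic acid cycle list (camera adjusted p = 2.08e-11), 18 of 22 genes fell when adjusted over the list alone, and 8 were called, all lower, over all genes in the 6-library comparison. Idh3a and Idh3b, subunits of the NAD-dependent isocitrate dehydrogenase, differed by -0.76 ± 0.17 and -0.60 ± 0.15 (adjusted p = 0.0981 and 0.108, and 0.0425 and 0.0335 with 6 libraries). In the fatty acid oxidation list (camera adjusted p = 2.08e-11), 18 of 22 genes fell when adjusted over the list alone, and the 6-library comparison called 10, all lower. Etfdh, which passes electrons from acyl-CoA dehydrogenases to ubiquinone, differed by -0.87 ± 0.13 (adjusted p = 0.0874, and 0.0289 with 6 libraries). Acadvl and Acadl, the very long-chain and long-chain acyl-CoA dehydrogenases, differed by -1.17 ± 0.22 and -0.65 ± 0.16. With an estimated correlation the adjusted p was 0.334 for both lists.

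The peroxisomal list (camera adjusted p = 8.83e-10) had 15 of 18 genes that fell when adjusted over the list alone and 4 called, all lower, in the 6-library comparison. Ehhadh, the bifunctional enzyme of peroxisomal beta-oxidation, differed by -1.50 ± 0.26 (adjusted p = 0.0915, and 0.0313 with 6 libraries). Hsd17b4, the second such enzyme, differed by -0.80 ± 0.14, and Cat, catalase, by -0.84 ± 0.15. With an estimated correlation the adjusted p of this list was 0.310. Mitochondrially encoded mRNAs (camera adjusted p = 2.13e-09, and 0.334 with an estimated correlation) had 11 of 13 genes that fell when adjusted over the list alone and 2 called in the 6-library comparison. mt-Nd5, a complex I subunit, differed by -1.08 ± 0.18 (adjusted p = 0.0874, and 0.0406 with 6 libraries). All mitochondrial transcripts together took 21.7% ± 2.65 of the counts in WT and 16.6% ± 1.34 in KO (SD, n = 4). The exact permutation p of this difference was 0.0286, the smallest that 4 against 4 can give.

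**Figure D3:**
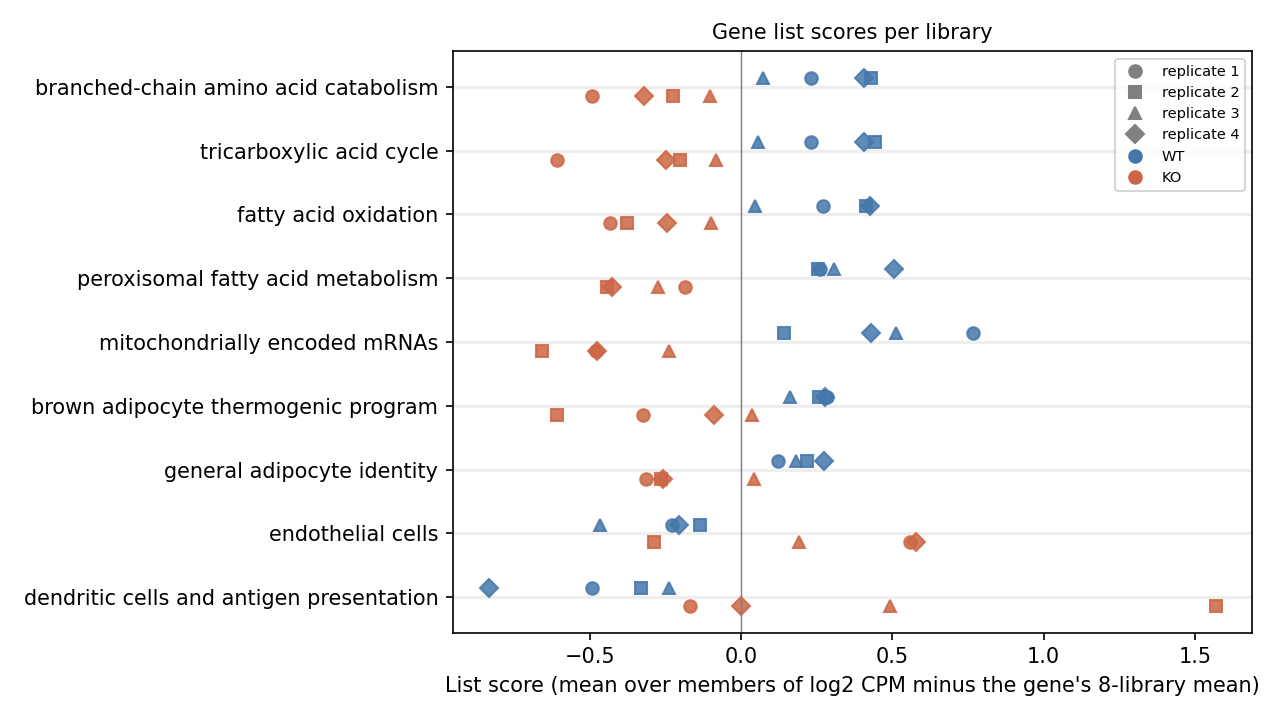
List scores (x axis, mean over the measured members of log2 CPM minus the gene's mean over all 8 libraries) of 9 gene lists (y axis). Each point is 1 library, blue for WT and orange for KO, with a symbol per replicate. In the first 7 lists all 4 KO points lie below all 4 WT points, and in the endothelial list 3 of 4 KO points lie above them. In the dendritic cell list all 4 KO points lie above all 4 WT points, and KO replicate 2 has the highest score, 1.57.

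Nuclear genes for the respiratory chain were measured as separate lists. Of 39 genes of complexes II to V, 35 lay lower in KO, with a median of -0.26 (camera adjusted p = 1.06e-05, and 0.513 with an estimated correlation), and 0 passed when adjusted over the list alone. Without KO replicate 1 the median was -0.16. These values hold for TMM scaling. With total library size only, the median of all genes moved from 0.00362 to 0.264, about the size of this list's median. Uqcrc2, a core subunit of complex III, differed by -0.79 ± 0.18 (adjusted p = 0.0981, and 0.0334 with 6 libraries). Of 36 complex I genes, 27 lay lower with a median of -0.13 (camera adjusted p = 0.00210, and 0.70 with an estimated correlation), and Ndufs1 had the smallest p, with -0.65 ± 0.14. The complex I median was -0.07 without WT replicate 2 (camera adjusted p = 0.0524) or KO replicate 2, -0.08 without KO replicate 1 and -0.20 without KO replicate 4. In the list of mitochondrial dynamics and protein quality, 22 of 26 genes lay lower and 9 fell when adjusted over the list alone, with Bnip3l, a mitophagy receptor, at -0.53 ± 0.11. That list had a camera adjusted p of 2.75e-05, and 0.334 with an estimated correlation.

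The brown adipocyte thermogenic list had 24 of 28 genes lower in KO and a median of -0.52 (camera adjusted p = 5.05e-05, and 0.334 with an estimated correlation). Adjusted over the list alone, 7 fell and 1 rose. Ucp1 (ENSMUSG00000031710) had a log2 fold change of -0.88 ± 0.25 (adjusted p = 0.131, and 0.0581 with 6 libraries), and all 4 KO libraries lay below all WT libraries. Elovl3, a fatty acid elongase of brown fat that cold induces, differed by -1.26 ± 0.26 (adjusted p = 0.0981, and 0.0289 with 6 libraries). Pdk4, which restrains glucose oxidation, differed by -0.90 ± 0.22 and Slc25a20, the mitochondrial carnitine carrier, by -0.69 ± 0.17. Ppargc1a, a coactivator of mitochondrial biogenesis, differed by -0.78 ± 0.29 (adjusted p = 0.187). Cidea averaged 2495 ± 239 CPM in WT and 2343 ± 178 CPM in KO, a log2 fold change of -0.09 ± 0.12 (adjusted p = 0.686) that was 0.16 with scaling by total counts alone. Prdm16 differed by 0.34 ± 0.55 (adjusted p = 0.743). Dio2, the deiodinase that activates thyroid hormone, ranged from 135 to 245 CPM in WT and from 19.1 to 303 CPM in KO. It differed by -0.15 ± 0.79 with all libraries and by 0.12 ± 0.57 with 6 (adjusted p = 0.928 and 0.921).

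Beta-adrenergic and acute cold response genes lay lower in 19 of 23 cases, with a median of -0.59 (camera adjusted p = 0.00128, and 0.359 with an estimated correlation), and 3 fell when adjusted over the list alone. Without WT replicate 1 the median was -0.36 (camera adjusted p = 0.0171). Prkar2b, a regulatory subunit of protein kinase A, differed by -0.81 ± 0.17 (adjusted p = 0.0981, and 0.0419 with 6 libraries) and Adrb1, the beta-1 adrenergic receptor, by -1.13 ± 0.32 (adjusted p = 0.126, and 0.0335). Adrb3, the adipocyte beta receptor, differed by -0.85 ± 0.33 (adjusted p = 0.194).

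General adipocyte genes lay lower in 16 of 18 cases, with a median of -0.48 (camera adjusted p = 2.22e-05, and 0.334 with an estimated correlation), and 8 fell when adjusted over the list alone. The lipid droplet protein Cidec differed by -0.54 ± 0.11 (adjusted p = 0.0915, and 0.0470 with 6 libraries) and Adipoq, the gene of the hormone adiponectin, by -0.53 ± 0.14 (adjusted p = 0.118). Pparg, the master regulator of adipocytes, differed by 0.18 ± 0.16 (adjusted p = 0.523) and Lep by -1.07 ± 0.67 (adjusted p = 0.362). The lipolysis list (14 of 15 lower, median -0.28) had a camera adjusted p of 8.92e-05, and 0.334 with an estimated correlation. Fatty acid uptake and triglyceride synthesis (16 of 20 lower, median -0.25) had a camera adjusted p of 0.0114, and 0.473 with an estimated correlation. In that list Slc27a2, a fatty acid transporter and acyl-CoA synthetase, differed by -0.76 ± 0.14 and Acsl1, which activates long-chain fatty acids, by -0.78 ± 0.19. Without KO replicate 2 the camera adjusted p of the fatty acid uptake and triglyceride synthesis list was 0.0966. Gpihbp1, which anchors lipoprotein lipase on capillary endothelium, lay higher in KO, at 0.61 ± 0.20 (adjusted p = 0.153, and 0.0406 with 6 libraries). Glycolysis genes lay lower in 16 of 19 cases (median -0.46, camera adjusted p = 0.00544, and 0.467 with an estimated correlation). Without KO replicate 1 the glycolysis median was -0.29. Pfkfb3, which sets fructose 2,6-bisphosphate, differed by -0.86 ± 0.19 and Pgam1 by -0.88 ± 0.23.

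Endothelial markers had a camera adjusted p of 1.40e-05, and 0.473 with an estimated correlation. Adjusted over the list alone, 10 of 20 rose with all 8 libraries and 15 of 20 in the 6-library comparison, where 7 were called over all genes. Esam, an endothelial adhesion molecule, averaged 197 CPM in WT and 315 CPM in KO, a log2 fold change of 0.67 ± 0.17 (adjusted p = 0.103, and 0.0334 with 6 libraries). Tie1, Emcn and Sox17 differed by 0.90 ± 0.25, 0.67 ± 0.24 and 0.78 ± 0.24, with adjusted p of 0.0289, 0.0289 and 0.0346 with 6 libraries. The endothelial score of KO replicate 2 lay within the WT range, and those of the other 3 KO libraries lay above all WT libraries. Of 18 fibroblast and progenitor markers, 7 lay higher (median -0.26, camera adjusted p = 0.389). Their median was -0.06 without WT replicate 3 and -0.03 in the 6-library comparison. Cd34, which endothelial cells also carry, differed by 0.64 ± 0.18 (adjusted p = 0.127, and 0.0385 with 6 libraries), and Col1a1 differed by -0.47 ± 0.32 (adjusted p = 0.407). Mural and smooth muscle markers had a median of 0.20 (camera adjusted p = 0.687), which was 0.04 without KO replicate 1, 0.13 without WT replicate 2 and 0.31 without KO replicate 2 or WT replicate 4.

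In each of the dendritic cell, T and NK cell, interferon response, B and plasma cell and macrophage lists the median lay higher in KO, and KO replicate 2 had the highest score. All 4 KO scores lay above all WT scores for dendritic cells and for B and plasma cells (exact permutation p = 0.0286 each, adjusted 0.101). For T and NK cells and for macrophages 2 KO scores did so, and for interferon response 1. Dendritic cell and antigen presentation genes lay higher in 14 of 14 cases (median 1.26, camera adjusted p = 5.05e-05, and 0.406 with an estimated correlation), and 10 rose when adjusted over the list alone. Without KO replicate 2 their median was 0.74, and in the 6-library comparison it was 0.76, with 12 of 14 higher and 6 that rose when adjusted over the list alone. Clec9a, a receptor of conventional dendritic cells, differed by 1.08 ± 0.25 (adjusted p = 0.10). H2-Ab1, an MHC class II chain, and Zbtb46 were called in the 6-library comparison, with log2 fold changes of 1.10 and 0.82 (adjusted p = 0.0438 and 0.0289). T and NK cell genes had a median of 1.98 with all libraries and 0.83 in the 6-library comparison (camera adjusted p = 1.83e-05, and 0.513 with an estimated correlation), and Klrb1c had the smallest p (3.45 ± 0.94). Cell cycle genes had medians of 1.25 and 0.43 (camera adjusted p = 5.06e-05, and 0.584 with an estimated correlation), with Cdc20 at 1.21 ± 0.34. Without KO replicate 2 alone the T and NK cell median was 0.79 and the cell cycle median 0.36. Interferon response genes had medians of 0.85 and -0.21 (camera adjusted p = 0.00423, and 0.70 with an estimated correlation). Without KO replicate 2 alone the interferon response median was -0.09 and its camera adjusted p 0.486, and without WT replicate 1 the median was 1.45. Rsad2, an interferon-induced antiviral enzyme, was the member called in the 6-library comparison (0.94 ± 0.16, adjusted p = 0.0316). B and plasma cell genes lay higher in 9 of 9 cases (median 0.66, camera adjusted p = 0.00980, and 0.334 with an estimated correlation), with Jchain at 1.34 ± 0.64 (adjusted p = 0.259). Without KO replicate 2 the camera adjusted p of the B and plasma cell list was 0.0677, and in the 6-library comparison it was 0.102, with 7 of 8 higher and Jchain at 0.66. Macrophage genes were not called (median 0.47, camera adjusted p = 0.0543), and Adgre1, the F4/80 antigen, differed by 0.47 ± 0.34 (adjusted p = 0.423). The macrophage median was 0.13 without KO replicate 2 (camera adjusted p = 0.794). The list was called without KO replicate 1 (0.00421), KO replicate 4 (0.0110) or WT replicate 3 (0.0315). It was also called with the stricter filter, with limma-voom, with the replicate block, and with length and GC trends removed.

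Integrin and focal adhesion components, the group to which Kindlin-2 belongs, did not pass the test: 17 of 31 lay higher, with a median of 0.11 (camera adjusted p = 0.389). Without KO replicate 2 the camera adjusted p of the integrin and focal adhesion components list was 0.0497 (median 0.22), and in the 6-library comparison it was 0.0771. The list median was also 0.21 without WT replicate 3 (camera adjusted p = 0.508), and 0.08 without WT replicate 4 (0.503) or KO replicate 1 (0.695). Ptk2, focal adhesion kinase, differed by 0.44 ± 0.13 (adjusted p = 0.131). Actn1, an actin cross-linker, and Itga6, an integrin chain, were called in the 6-library comparison, at 0.67 ± 0.12 and 0.66 ± 0.13. Basement membrane genes had a median of 0.14 (camera adjusted p = 0.370), and 0.29 without KO replicate 2 (camera adjusted p = 0.00306). Their median was 0.24 without WT replicate 3 (0.529) or WT replicate 4 (0.390), and 0.11 without WT replicate 2 (0.445). In the 6-library comparison the camera adjusted p was 0.00742, and 0.432 with an estimated correlation. In that list Sparcl1 and the laminin chain Lama5 were called in the 6-library comparison, at 0.60 ± 0.12 and 0.91 ± 0.13. The 3 remaining called lists had small medians. Oxidative stress and glutathione genes had -0.21 (camera adjusted p = 0.0232, and 0.473 with an estimated correlation). Autophagy and lysosome genes had -0.24 (0.0232, and 0.334), with Map1lc3a at -0.41 ± 0.14. Clock genes had -0.32 (0.0364, and 0.334), with Hlf at -0.70 ± 0.17. Leaving out 1 library ended each of these calls: for oxidative stress and glutathione without WT replicate 1 (0.0503), and for autophagy and lysosome without WT replicate 3 (0.0786, median -0.14). For circadian clock it did so without WT replicate 1 (0.0503), WT replicate 3 (0.0863, median -0.20) or KO replicate 2 (0.141).

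The rule for the genes with the largest changes named none with all 8 libraries, because no gene passed the threshold, and it was applied to the 6-library comparison, chosen after the data were seen. The highest rises were those of Cpne7, a calcium-dependent membrane-binding copine (log2 fold change 3.0 ± 0.44), the clone gene BB365896 (2.63 ± 0.47) and the glutathione transferase Gsta3 (2.02 ± 0.35). The next were Kcnc4, a potassium channel (1.83 ± 0.33), Ramp3, a partner of the calcitonin receptor family (1.72 ± 0.26), Cyp1a1, a cytochrome P450 (1.72 ± 0.21), and Lhx6 (1.46 ± 0.27). Gipc3, Tmem255b and Ssu2 followed with 1.36, 1.34 and 1.30. With all 8 libraries Kcnc4 had the opposite sign, -0.47 ± 1.06, and without WT replicate 3 alone its value was 1.47. Cyp1a1 (ENSMUSG00000032315) had the smallest adjusted p with all libraries, 0.0800, at 1.94 ± 0.22. It averaged 5.86 ± 1.18 CPM in WT and 22.6 ± 5.48 CPM in KO (SD, n = 4), and all 4 KO libraries lay above all WT libraries.

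Falls in the 6-library comparison were ranked among called genes that met the same rule, including a mean log2 CPM of at least 1. The deepest were those of Hmga1b (-2.87 ± 0.57), mt-Atp8 (-1.94 ± 0.39) and Btc, the gene of the growth factor betacellulin (-1.85 ± 0.30). Hmga1b is a near-identical copy of another gene and mt-Atp8 overlaps its neighbour mt-Atp6, so both values are uncertain. Txlnb followed with -1.62 ± 0.19, and with all libraries its value was -4.09 ± 1.23, with 177 CPM in WT replicate 3 against 11.3 CPM at most in the other WT libraries. Bckdha, the acyl-CoA synthetase gene Acsm3, Adrb1 and the glutaredoxin gene Glrx fell by 1.48, 1.46, 1.45 and 1.45 on the log2 scale. Acadvl and Tmem25 completed the list, with -1.41 and -1.39. All 20 genes had adjusted p between 0.0289 and 0.0475 in this comparison.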

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

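The values below were picked because 1 library of a group lay far from the other 3, by a rule fixed beforehand that was applied to 230 groups of 4 values and picked 20, where about 12 would come by chance. Of the 20, 6 lay in WT replicate 3 and 8 in KO replicate 2. Several of the genes were named because the 6-library comparison, which left out both these libraries, called them. Such a call favours genes that vary little within the groups of the other libraries. It thus favours flags in the libraries left out, so the figure of 12 gives no fair comparison with chance. The tests on skeletal muscle, on interferon transcripts, and on the share or dilution of adipocytes were chosen after the result was seen.

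In WT replicate 3, Cidea was 2138 CPM (other WT libraries 2598 to 2635), Txlnb 177 (10 to 11.3), Glrx 24.6 (50.9 to 51.7), Slc27a2 317 (425 to 436) and Zbtb46 46.4 (62.1 to 64.1). Its lipolysis list score was -0.00258 (0.20 to 0.24). In KO replicate 2, Elovl3 was 6.84 CPM (other KO libraries 13.0 to 14.7), Lhx6 6.81 (15.8 to 18.4), Hmga1b 3.64 (1.16 to 1.38), Map1lc3a 249 (319 to 334) and Actn1 26.7 (47.2 to 52.3). Its list scores were 2.09 for interferon response (-0.38 to -0.09), -0.22 for integrin and focal adhesion components (0.12 to 0.15) and -0.38 for basement membrane (0.17 to 0.27). Mccc2 was 68.6 CPM in KO replicate 3 (57.9 to 59.6), Cidec 816 in KO replicate 4 (924 to 943) and Cdc20 3.0 in WT replicate 1 (1.5 to 1.67). The general adipocyte identity score was 0.0415 in KO replicate 3 (-0.31 to -0.26). In KO replicate 1 the glycolysis score was -0.65 (-0.15 to -0.05) and the oxidative stress and glutathione score was -0.23 (-0.04 to 0.00).

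Whether the skeletal muscle transcripts in WT replicate 3 came from muscle carried into the sample remains open. All 18 tested members of the list, 100%, were highest in that library, which restates the high share and decides nothing. Ucp1, at 81% of the median of the other WT libraries, argues against a sample of a tissue that lacks Ucp1 under this label. It cannot exclude a different depot that expresses Ucp1, since the labels name no depot. No biological explanation was tested for this library.

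For the interferon and T cell transcripts in KO replicate 2, whether loss of Kindlin-2 raises interferon transcripts in every KO mouse remains open, because the mean score of the other 3 KO libraries was 0.15 above that of WT without lying above all 4 WT libraries. In the fit without KO replicate 2 the list median was -0.09, and in the 6-library comparison -0.21 with 18 of 24 members lower. An infection or immune response of this mouse was not tested.

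The lower energy metabolism lists and the higher endothelial list in KO were not produced by gene length and GC content, since each of the 6 medians kept at least 95.5% of its size. Removing mitochondrially encoded genes left at least 97.3% of each of 5 medians but moved the median of all genes only from 0.00362 to 0.02, so it decides nothing about scaling. Uniform dilution of adipocyte transcripts remains open. The median of Pparg, Cidea, Plin1, Cidec, Fabp4 and Lipe lay 0.41 above that of the fatty acid oxidation list (exact permutation p = 0.0286). In the difference of the 2 scores all 4 KO libraries lay above all WT libraries. This met the bound written for the test, so these 6 markers did not fall as far as that list. The markers were chosen after the result was seen, however. The median of the general adipocyte identity list lay only 0.14 above that of the fatty acid oxidation list. A lower share of adipocytes that raises other cell types alike remains open too: the endothelial minus fibroblast score differed by 0.77, with an exact permutation p of 0.0571. An effect of Kindlin-2 loss on these genes is open as well.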

How the results depend on the processing

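The count of genes past an adjusted p of 0.05, 0 with edgeR, was also 0 with DESeq2 factors, upper-quartile factors, the stricter filter, limma-voom, non-robust dispersion, removal of mitochondrially encoded genes or of list members, both fold change thresholds and an adjusted p under 0.01. It was 882 (858 higher, 24 lower) with total library size only, where the median log2 fold change of all genes was 0.264 instead of 0.00362. A shift of that size is near the smaller list medians, such as -0.26 for complexes II to V, so their direction may depend on the scaling. The count of genes was 1 (1 higher) without a filter, 1113 (511 higher, 602 lower) with DESeq2 on the unfiltered genes and 911 (408 higher, 503 lower) with quality weights. Without both libraries it was 461 (253, 208), with DESeq2 1527 (754, 773) and with quality weights 1485 (740, 745). At an adjusted p under 0.10 it was 249 (98, 151). Leaving out 1 library gave 0 to 361 genes, 0 to 238 higher and 0 to 123 lower: 361 without KO replicate 2, 3 without WT replicate 4, 1 without WT replicate 1 and 0 without each of the others. Of the 461 genes, 365 were also called with quality weights and 280 with DESeq2 on 8 libraries. The cause of the differences between tests was not tested.

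With a replicate block the counts were 0 genes, 0 higher and 0 lower, and Fermt2 was -0.46 (adjusted p = 0.183). Deviations from the group means correlated by -0.05, 0.04, -0.13 and 0.22 between the WT and KO samples of the same number. The KO sample with the highest correlation had the same number for WT replicates 2 and 4, but not for 1 and 3. So few samples cannot show whether the numbers pair them.

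Fermt2 kept its direction under all alternatives run, from -0.53 (without KO replicate 1) to -0.19 (total library size only), and passed the threshold with DESeq2 alone (-0.46, adjusted p = 0.0336). Among the 78 genes examined, 17 of 1790 alternative values reversed. Dio2 (-0.15) was 0.0869 with total library size only, 0.22 with quality weights, and without both libraries 0.12 by edgeR, 0.12 by DESeq2 and 0.45 with quality weights. With 1 library left out Dio2 ranged from -0.59 to 0.23. With total library size only Cidea was 0.16 and Fabp4 0.0948. Kcnc4 (-0.47) was 0.20 with limma-voom, 1.38 with quality weights, 0.23 with a replicate block, and without both libraries 1.83 by edgeR, 1.82 by DESeq2 and 2.01 with quality weights. With 1 library left out Kcnc4 ranged from -0.82 to 1.47.

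The count of gene lists, 23, was 0 with an estimated correlation and 9 with fry. Among the other settings it ranged from 18 (both libraries left out, quality weights) to 30 (without KO replicate 1). With total library size only it was 21. The calls lost there were complex I, B and plasma cells, interferon response, oxidative stress and glutathione, and autophagy and lysosome. With quality weights it was 22, and complex I, fatty acid uptake and triglyceride synthesis, and circadian clock were lost. The 7 calls lost without both libraries and with quality weights included cell cycle and proliferation. Without both libraries it was 22, of which 20 were shared; B and plasma cells, interferon response and circadian clock were lost, and actin cytoskeleton and basement membrane were gained. Depth limits were not tested by thinning the counts; every library had at least 33672272.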

Other observations

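Several further lists were not called with all 8 libraries. Actin cytoskeleton and contractility genes had a median log2 fold change of 0.13 (camera adjusted p = 0.0818). In the 6-library comparison 20 of 23 lay higher (0.0116, and 0.432 with an estimated correlation), and the list was also called with quality weights and without WT replicate 3 or KO replicate 2. Fibrillar collagens and extracellular matrix genes had -0.26 (0.0839), and -0.03 in the 6-library comparison. They were called with total library size only, with the replicate block, with length and GC trends removed, and without WT replicate 2, KO replicate 1 or KO replicate 3. P53 targets and apoptosis genes had 0.33 (0.0504). They were called without a filter, with the stricter filter, with limma-voom, with the replicate block, with list members removed, and with length and GC trends removed. They were also called without WT replicate 2, WT replicate 3, KO replicate 1, KO replicate 3 or KO replicate 4. Insulin signalling genes had -0.13 (0.0838), and 2 of 20 fell when adjusted over the list alone. They were called without KO replicate 3 and with length and GC trends removed. De novo lipogenesis genes had 0.03 (0.934), and -0.35 in the 6-library comparison with 12 of 18 lower (0.0771). YAP/TAZ target genes had -0.07 (0.977), and 0.10 in the 6-library comparison, and unfolded protein response genes 0.06 (0.682), called without KO replicate 1. White adipocyte markers had -0.15 (0.597) (0.16 in the 6-library comparison), and lymphatic endothelial markers -0.65 (0.135), called with total library size only, with the replicate block and without KO replicate 1.

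Other splits of the 8 libraries into 4 and 4 were tested. The count of 0 genes past the adjusted threshold by edgeR was reached by 35 of 35 splits, as a count of 0 must be, so this says nothing about the grouping; the highest other was 1. In the real grouping 2993 genes had an unadjusted p under 0.05, and DESeq2 called 1113. For genes with an unadjusted p under 0.05, 1 of 35 splits, the real one, gave 2993, and the highest other gave 1572. This met the bound set beforehand, a share under 0.05. Since 1 of 35 is the smallest share these splits can give, chance is less likely but not excluded. With quality weights the real split gave 911 and the highest other 196 (1 of 35), with the same limit. For gene lists chance is not excluded, since 7 of 35 splits gave at least the 23 of the real one and the highest other gave 29. Without both libraries there were 10 splits, too few for a share under 0.05; the real split gave 461 and the highest other 0 (1 of 10).

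The hypothesis that aryl hydrocarbon receptor targets move together with Cyp1a1 was tested on 5 further targets. Their median log2 fold change was -0.0218, with 2 above 0 and a camera p of 0.486. A median at or below 0 was the bound set beforehand against the hypothesis, and it was met. The value lay within the standard error over the members, 0.19, a condition not in that bound, so the test was taken as undecided. Cyp1b1 was 0.67 (edgeR adjusted p = 0.105). The hypothesis that the higher endothelial list reflects angiogenic tip cells was tested on 9 markers, 8 of them above 0. Their median was 0.54, which differed from the endothelial median by -0.0207. A median below the endothelial one was the bound set beforehand against this hypothesis, and it was met. The difference again lay within the standard error over the members, 0.19, so this test was taken as undecided too.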
